A study of Caenorhabditis elegans with 4 samples.

How the data were processed

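The data are 4 arrays of 2 colours, each with messenger RNA from a preparation of him-5 adult males in channel 2 and wild-type mixed-stage reference RNA in channel 1, per the labels. The reference was not hybridised against itself, so the test is whether the mean log ratio differs from 0, and it leaves out the reference's own spread. No dye is named, and no dye swap is recorded in the labels, so that a bias of single genes towards 1 dye stays in every ratio. Whether the reference was the same RNA on every array is not stated, and the labels word it in 2 ways.

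The deposited values are log2 ratios, which the authors had already scaled per array; the method is not given in the sources used here, nor are the image analysis, background correction and spot filters. The base of the logarithm was taken from the values themselves. On each array, 100% of the values below a ratio of 3 were whole multiples of 0.001 when raised as powers of 2 (within 0.01 of that step), against 2.2% to 2.6% for the natural or decimal base. The array medians were -0.01, 0.05, -0.001 and 0.07, close enough to one another that values were used as deposited. The direction of the ratio is not stated in the table, and males over reference is likely from the series title, the descriptions and the channel order. Spot intensities were not used here, so a filter on faint spots or a correction that depends on brightness could not be applied. Any offset of faint or bright spots that the authors' scaling left would remain in the values.

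Of 20000 probes, 19024 had values on 4 arrays, 622 on 3, 161 on 2, 115 on 1 and 78 on 0. Names came from the platform annotation, updated through gene identifiers to the symbols of assembly WBcel235. It gave 15655 probes 1 gene symbol, 198 several and 4147 none. Of the 15655, 15569 were matched by gene identifier and 7 by accession, and 79 kept the platform's symbol. Probes with several symbols or none stayed as unnamed features. Probes of the same gene were averaged per array, for 467 genes with up to 4 probes. Of 413 such genes with several measured probes, 62 had probe means more than 1 apart on the log2 scale, and 5 had probe means beyond 0.5 on both sides of 0. The files name no genome build, so no coordinates are given, and the assembly served only for names and for which genes neighbour each other.

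Features with values on at least 3 arrays (19214 of 19513) were tested with limma 3.58.1 in R 4.3.3. An intercept was fitted with lmFit and moderated with eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested features, and a feature was called at an adjusted p under 0.05. An exact sign-flip test of single genes could not go below 0.125 with 4 arrays. A list of 23 gene sets was fixed before the data were examined, and sets with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 22 lists. Camera and fry used only genes with values on 4 arrays. Classes of gene names with at least 10 genes were tested in the same way. The estimated correlation rests on 4 arrays and thus on few residual degrees of freedom. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

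The steps were tested on simulated data with the spread of the real features. For males against reference, over 19214 features of which 200 were changed, 52% of the 2-fold changes and 100% of the 4-fold changes were called with the right sign, and 12 unchanged features were called. With 8777 features changed 4-fold, 99.8% were called and 2.5% of the calls were false. The simulated noise was independent between features, whereas genes in the data varied together (estimated correlation 0.788 in the ribosomal protein list). The median absolute mean log2 ratio of the data was 0.55, below the simulated changes. These shares therefore need not hold for the real calls.

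Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest called ratios in each direction among genes with values on 4 arrays and a single sign, up to 3 called genes with the largest absolute ratio and a single sign from each list, and 24 genes fixed in advance. Of these 24, fog-1, mab-3, tra-1 and tra-2 had no probe matched and tested here. Other genes are named where a list had few members of a kind, and were chosen after their values were seen.

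Alternatives fixed in advance were median centring, scale and quantile normalization between arrays, centring on ribosomal protein genes, other limits on missing values, robust eBayes, array weights, every probe on its own, a stricter adjusted p of 0.01, other set tests, leaving out each preparation in turn, and the period of hybridization as a covariate. The sample titles divide the arrays into an earlier and a later pair, preparations 1 and 2 against 3 and 4. Each pair holds arrays of the only group, so no comparison within a pair was made. Centring on chemoreceptor genes, and the period as a random block, were added after the data were seen. The scanner files were not used here.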

Results

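Adult males of the nematode Caenorhabditis elegans were compared with a wild-type reference on 4 DNA microarrays of 2 colours. The males carried a mutation in him-5, a gene whose loss causes errors of X-chromosome segregation in meiosis and so yields many male offspring. Each array held messenger RNA from a different preparation of males beside reference RNA from worms of mixed stages, so that preparations 1 to 4 make up the only group. Per array, 19424 to 19761 of the 20000 probes had a log2 ratio. The labels do not say whether the preparations came from separate cultures, and p-values therefore measure only the spread between these preparations, which may be technical. Precision is limited by the number of arrays.

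The comparison asks which transcripts are more or less abundant in adult males than in a mixed population of wild-type worms. Sex, the him-5 mutation and stage differ together between the 2 sides, and no change can be assigned to any of them alone. Values are given as males over reference. By the labels that direction is likely and not settled, because no dye is named: it rests on the series title, the sample descriptions and the order of the channels. Of the checks fixed in advance, the major sperm protein genes had a median log2 ratio between 4.01 and 5.08 on the 4 arrays, which goes with that direction and argues against the reverse. The medians of the other sperm genes (1.89 to 2.91) and of the oocyte genes (-1.06 to -0.76), which were not among those checks, argue against the reverse too. The median of the 3 vitellogenin genes, which encode yolk proteins of adult hermaphrodites, was 0.08 to 0.98 and went against it. On every array that median was the value of vit-5 alone, with 0.98 on preparation 2 and 0.08 to 0.35 on the others. Within that list vit-2 was lower in males at -1.33 ± 0.87 (SD, n = 4), vit-6 was higher at 0.91 ± 0.44 (SD, n = 4), and vit-5 was not called at 0.39 ± 0.41 (SD, n = 4). The vitellogenin median was 0.39 and the mean -0.01. Without preparation 2 that median was 0.19, and it was -0.01 or 0.04 with arrays centred on ribosomal protein genes or chemoreceptor genes. The call of vit-6 was lost without preparation 3 (log2 ratio 0.76, adjusted p = 0.0643) and with arrays centred on ribosomal protein genes (0.51, adjusted p = 0.24) or chemoreceptor genes (0.56, adjusted p = 0.0879). Without preparation 1, vit-2 stood at -0.91 and was still called.

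Most sperm genes were higher in males, 29 of 30 major sperm protein genes and 54 of 58 other sperm genes, while 38 of 56 oocyte genes, 28 of 46 meiotic genes and 37 of 58 cell cycle genes were lower. These 5 lists passed camera at a preset correlation and not with an estimated correlation, where adjusted p = 0.342 for each. With 4 arrays, the latter test gave 0 of the 22 lists an unadjusted p under 0.05, and so cannot tell stronger lists from weaker ones here. Fry called all 5 lists in the same directions (adjusted p from 0.00436 to 0.0103). The log2 ratio of him-5 itself was -2.28 ± 0.62 (SD, n = 4, adjusted p = 0.000492), a mean 4.84-fold below the reference, with single arrays from -3.11 to -1.61. The probe's position relative to the him-5 mutation is not given in the sources used here, so this value does not check the strain. Of 19214 features tested (15059 named genes and 4155 probes without a single gene name), 4242 were called higher in males and 4535 lower at an adjusted p under 0.05 by limma. At least 2-fold differences were called for 2534 higher and 2328 lower, and at least 8-fold differences for 479 higher and 39 lower. Thus 48.3% of the calls were higher. With arrays centred on ribosomal protein genes, which moved the median of all features by -0.40, 26.4% of the calls were higher, and with arrays centred on chemoreceptor genes, which moved it by -0.34, 26% were. Neither centring moves the arrays alike: the ribosomal one subtracts 1.10 from preparation 2 and 0.04 to 0.34 from the others. The chemoreceptor one subtracts 0.77 and 0.14 to 0.27. Calls can therefore also end through a changed spread between the arrays. Without preparation 3 the calls fell to 2782 higher and 3010 lower.

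The 10 named genes with the largest positive ratios included K12H6.4 at 6.03 ± 0.39 (SD, n = 4), irg-5 at 5.93 ± 0.42 (SD, n = 4), F56D2.8 at 5.84 ± 0.55 (SD, n = 4) and K12H6.9 at 64.2-fold with an SD of 1.19 on the log2 scale. On preparation 4, irg-5 lay apart at 5.30. The C-type lectin genes clec-197 and clec-208 stood at 5.59 ± 0.24 and 5.32 ± 0.45 (SD, n = 4), which are 48.2-fold and 40.0-fold. The same set held C16C8.9 at 5.56, msp-50 at 5.41, C17F3.1 at 6.17 with arrays from 4.76 to 9.49, and Y67A6A.1 at 5.66 with arrays from 2.57 to 8.76. Without preparation 4 the mean of C17F3.1 was 5.06, and that of Y67A6A.1 was 6.69 without preparation 2 and 4.63 without preparation 3. The 10 with the most negative ratios were led by hsp-12.6, a small heat shock protein gene, at -4.75 ± 0.24 (SD, n = 4). They also held B0507.8 at -3.98 ± 0.36 (SD, n = 4), F40G12.5 at -3.94 ± 0.54 (SD, n = 4) and the collagen gene col-164 at -3.82 ± 0.22 (SD, n = 4). The others were T22F3.11 at -3.75, cup-16 at -3.73, C44B7.5 at -3.72, T14B1.1 at -3.62, ora-1 at -3.52 and scl-2 at -3.51. Adjusted p in both sets lay between 2.61e-05 and 0.0015.

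Of 30 major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, 29 were higher (29 adjusted over the list alone) with a list median of 4.72. The strongest were msp-50 at 5.41 ± 1.10, msp-59 at 5.19 ± 0.58 and msp-152 at 5.18 ± 0.73 (SD, n = 4). On preparation 4, msp-59 lay apart at 4.33, and msp-38 was not called at 0.38 ± 0.29 (SD, n = 4). Members of this family are nearly identical in sequence, and a probe may read several of them. The list passed camera with an adjusted p = 7.71e-22, and did not with an estimated correlation, where adjusted p = 0.342. Of 58 genes of spermatogenesis and sperm function, 54 were higher and none lower (54 higher and 1 lower adjusted over the list alone), with a median of 2.62 and a camera adjusted p = 2.75e-20, against adjusted p = 0.342 with an estimated correlation. Among them were ssp-16 at 5.29 ± 0.75, the sperm phosphatase genes gsp-3 at 4.57 ± 0.16 and gsp-4 at 4.35 ± 0.21, and spe-11 at 2.73 ± 0.56, which encodes a protein that sperm bring into the egg (SD, n = 4). nspd-1 stood at 5.29 ± 1.87, nspd-7 at 4.66 ± 0.67 and fer-1 at 2.08 ± 1.24 (SD, n = 4). The arrays of nspd-1 ran from 3.62 to 7.80, and without preparation 1 its mean was 4.45. On 3 arrays spe-9 stood at 1.72 ± 1.07 (SD, n = 3), and its call was lost with arrays centred on ribosomal protein genes (1.29, adjusted p = 0.119) or chemoreceptor genes (1.35, adjusted p = 0.0912). The members that were not called were spe-27, zipt-7.1, swm-1 and spe-39, at 0.23, 0.10, -0.35 and -0.46.

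**Figure D1:**
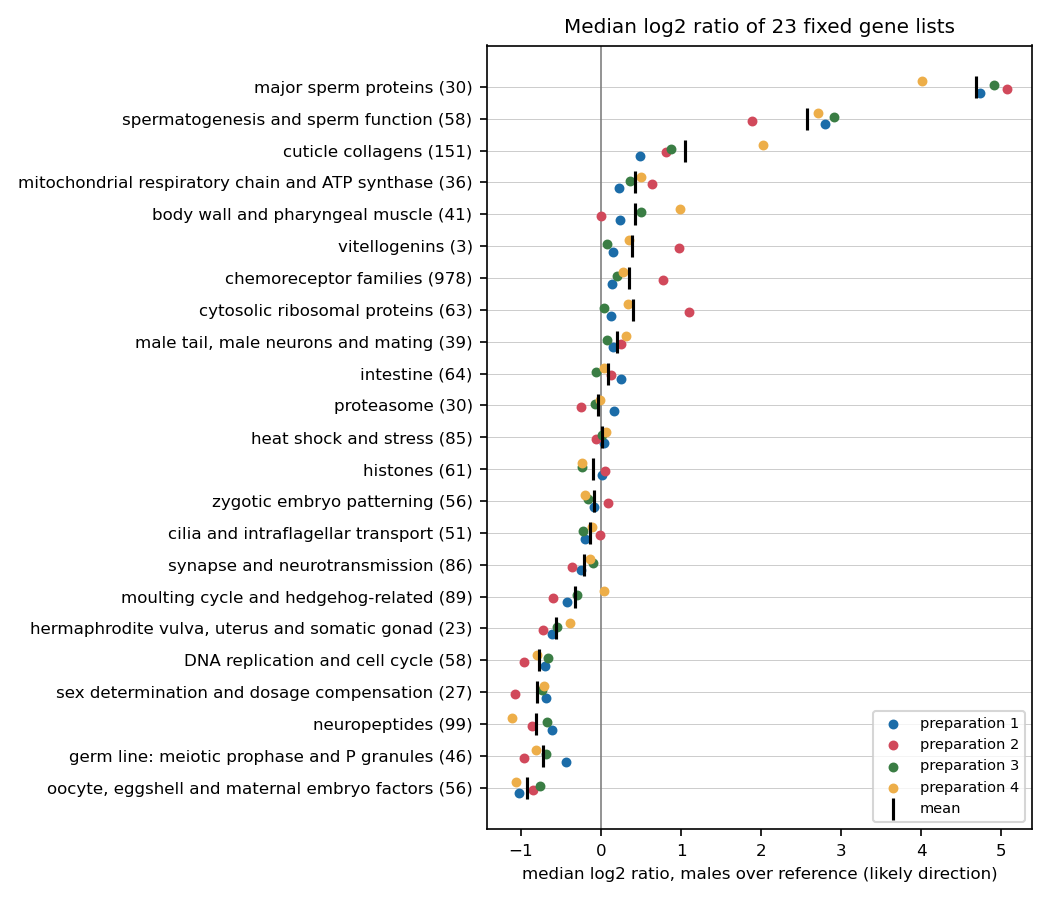
Median log2 ratio (males over reference, likely direction; x axis) of the 23 gene lists fixed in advance, with the number of measured genes in brackets (y axis). Coloured points are the 4 preparations and the black bar is their mean. Major sperm proteins (4.01 to 5.08) and sperm genes (1.89 to 2.91) lie above 0 on every preparation, and oocyte genes (-1.06 to -0.76) below it. Ribosomal protein genes reach 1.10 on preparation 2 alone. With arrays centred on ribosomal protein genes their own median is close to 0 by construction (-0.02), and that of chemoreceptor genes is also -0.02.

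Of 56 genes of the oocyte, eggshell and early embryo, 38 were lower and 5 higher (40 lower and 5 higher adjusted over the list alone), with a median of -0.97 and a camera adjusted p = 5.21e-07, or adjusted p = 0.342 with an estimated correlation. The caveolin gene cav-1 stood at -3.08 ± 0.42, the chondroitin proteoglycan gene cpg-3 at -2.38 ± 0.59 and egg-2 at -2.33 ± 0.22 (SD, n = 4). The yolk receptor gene rme-2 stood at -1.05 ± 0.59, cpg-1 at -1.42 ± 0.59 and lin-41 at -1.37 ± 0.30 (SD, n = 4). The 5 higher members, named after their values were seen, were cpg-18 at 1.69, cpg-19 at 0.99, puf-4 at 0.68, puf-12 at 0.63 and cpg-2 at 0.58. Of 46 genes of meiotic prophase and P granules, 28 were lower and 1, pgl-3 at 0.52, was higher (31 lower and 1 higher adjusted over the list alone). Their median was -0.81 and the camera adjusted p = 7.34e-06, or adjusted p = 0.342 with an estimated correlation. The DNA repair genes rad-50 and mre-11 stood at -2.33 ± 0.57 and -1.41 ± 0.30, and him-18 at -1.46 ± 0.49 (SD, n = 4). The Notch receptor gene glp-1 was lower at -0.85 ± 0.06 (SD, n = 4), and pgl-1 was not called at -0.13 ± 0.46 (SD, n = 4), with a value of 0.06 without preparation 2. The translational repressor gene gld-1 stood at -0.95 ± 0.63 (SD, n = 4) and lost its call without preparation 1 (-0.72, adjusted p = 0.0722) or preparation 2 (-0.82, adjusted p = 0.0675).

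Of 58 genes of DNA replication and the cell cycle, 37 were lower and 3 higher (the same counts adjusted over the list alone), with a median of -0.76 and a camera adjusted p = 1e-06, or adjusted p = 0.342 with an estimated correlation. The median was -1.165 with arrays centred on ribosomal protein genes. The DNA ligase gene lig-1 stood at -1.83 ± 0.25, cdk-8 at -1.68 ± 0.53 and the origin recognition gene orc-1 at -1.62 ± 0.20 (SD, n = 4). The higher members, named after their values were seen, were the spindle checkpoint genes bub-3 at 1.53 and bub-1 at 0.68 and the Aurora B kinase gene air-2 at 1.44. Of 61 histone genes, 11 were lower and 1 was higher (9 lower and 1 higher adjusted over the list alone), and the list did not pass (median -0.10, adjusted p = 0.143). It passed with arrays centred on ribosomal protein genes (-0.51, adjusted p = 0.0438) or chemoreceptor genes (-0.45, adjusted p = 0.0161) and with array weights (-0.14, adjusted p = 0.0493), and its median was -0.06 without preparation 4. For the values as deposited, camera with an estimated correlation gave the histone list an adjusted p = 0.672. The linker histone genes hil-3 and hil-7 stood at -2.49 ± 0.46 and -2.15 ± 0.39, and the histone H3 variant gene his-70 at 2.89 ± 0.42 (SD, n = 4). Of 56 genes of zygotic embryo patterning, 13 were lower and 7 higher (12 and 6 adjusted over the list alone), and the list did not pass (median -0.11, adjusted p = 0.341). Its median was -0.06 without preparation 1, -0.03 without preparation 4, and -0.51 or -0.46 with arrays centred on ribosomal protein genes or chemoreceptor genes. Members with the largest ratios were pes-2.1 at -2.29 ± 0.67, pes-2.2 at -2.16 ± 0.69 and sdz-6 at 2.22 ± 0.36 (SD, n = 4).

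Of 27 measured genes of sex determination and dosage compensation, 18 were lower and 2 higher (20 and 2 adjusted over the list alone), with a median of -0.78 and a camera adjusted p = 6.68e-05, or adjusted p = 0.342 with an estimated correlation. The higher members were fog-3, which is needed for germ cells to become sperm, at 2.15 ± 0.71 (SD, n = 4), and her-1, which encodes a secreted protein that directs male fate, at 1.77 ± 0.55 (SD, n = 3). Lower members included mix-1, a condensin gene, at -1.31 ± 0.31 (SD, n = 4). The list median lay apart on preparation 2, at -1.07, and was -1.18 with arrays centred on ribosomal protein genes. The male switch gene xol-1, which acts in the embryo, was not called at 0.47 ± 0.53 (SD, n = 4), and stood at 0.21 without preparation 2, on which it was 1.25. Of 23 genes of the hermaphrodite vulva, uterus and somatic gonad, 11 were lower and 1, cog-1 at 0.53, was higher (the same counts adjusted over the list alone), with a median of -0.40 and a camera adjusted p = 0.00363, or adjusted p = 0.342 with an estimated correlation. That median was -0.80 or -0.74 with arrays centred on ribosomal protein genes or chemoreceptor genes. The vulval morphogenesis genes sqv-1, sqv-7 and sqv-5 stood at -1.51 ± 0.50, -1.35 ± 0.40 and -1.14 ± 0.36 (SD, n = 4).

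Of 39 genes of the male tail, male neurons and mating, 15 were higher and 6 lower (the same counts adjusted over the list alone), but the list as a whole did not pass (median 0.21, adjusted p = 0.201), and its median was 0.05 without preparation 4, 0.08 with array weights, -0.19 with arrays centred on ribosomal protein genes and -0.14 with arrays centred on chemoreceptor genes. The insulin-like gene ins-31 stood at 4.57 ± 1.07 (SD, n = 3), the tubulin gene tba-6 at 4.02 ± 0.74 and cwp-2, a gene co-expressed with polycystins in male neurons, at 3.59 ± 1.04 (SD, n = 4). On preparation 2, cwp-2 lay apart at 2.05. The polycystin genes pkd-2 and lov-1, which male sensory neurons need for mating, stood at 2.72 ± 0.92 and 0.74 ± 0.33 (SD, n = 4). The call of lov-1 was lost without preparation 3 (0.76, adjusted p = 0.0622) or preparation 4 (0.59, adjusted p = 0.0516) and with arrays centred on ribosomal protein genes (0.34, adjusted p = 0.435) or chemoreceptor genes (0.40, adjusted p = 0.208).

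**Figure D2:**
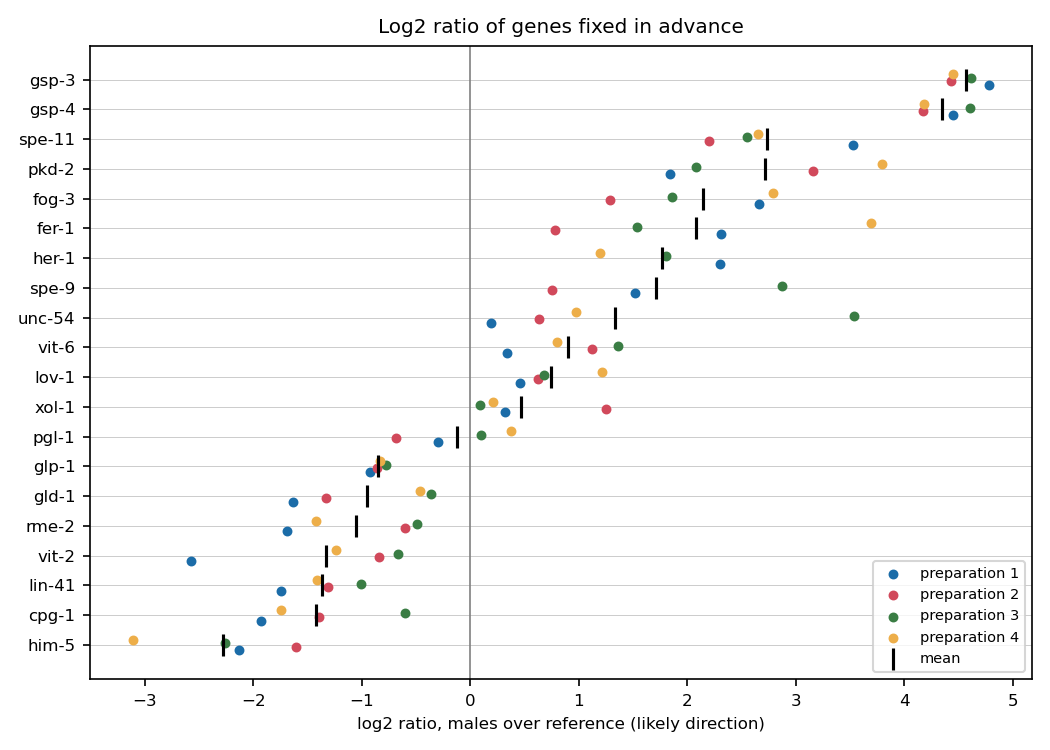
Log2 ratio (males over reference, likely direction; x axis) of the 20 measured genes of a set fixed in advance (y axis), with points for the 4 preparations (3 for her-1 and spe-9) and a black bar for their mean. The sperm genes gsp-3 and gsp-4 lie above 4 on every preparation and him-5 lies at -1.61 or below, while the points of unc-54 spread from 0.20 to 3.54.

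Cuticle collagen genes went both ways. Of 151, 79 were higher and 26 lower (84 and 27 adjusted over the list alone), with a median of 1.09 and a camera adjusted p = 1.09e-05, or adjusted p = 0.609 with an estimated correlation. The list median was 0.49, 0.81, 0.87 and 2.03 on preparations 1 to 4, and the overall median was 0.69 with arrays centred on ribosomal protein genes. The largest were col-62 at 4.50 ± 0.83, col-81 at 4.14 ± 0.83 and col-129 at 4.05 ± 0.66 (SD, n = 4), beside col-164 at the other end. Of 89 genes of the moulting cycle and hedgehog-related proteins, 30 were lower and 6 higher (the same counts adjusted over the list alone), with a median of -0.23 and a camera adjusted p = 0.00841, or adjusted p = 0.609 with an estimated correlation. Without preparation 4 their median was -0.44, and it was -0.63 or -0.57 with arrays centred on ribosomal protein genes or chemoreceptor genes. The hedgehog-related genes grl-3, wrt-10 and grl-9 stood at -2.84 ± 0.39, -2.46 ± 0.80 and -2.18 ± 0.23 (SD, n = 4), with grl-9 apart on preparation 2 at -2.52.

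Neuropeptide genes were mostly lower. Of 99, 57 were lower and 12 higher (59 and 14 adjusted over the list alone), with a median of -0.79 and a camera adjusted p = 1.02e-06, or adjusted p = 0.342 with an estimated correlation. The median was -1.185 with arrays centred on ribosomal protein genes. The insulin-like gene ins-35 stood at -2.65 ± 0.39, against nlp-4 at 2.88 ± 0.76 (SD, n = 4) and ins-31. Of 86 genes of synapses and neurotransmission, 27 were lower and 5 higher (25 and 4 adjusted over the list alone), with a median of -0.22 and a camera adjusted p = 0.0188, or adjusted p = 0.342 with an estimated correlation. Without preparation 2 the median was -0.14, and with array weights the call was lost (-0.09, adjusted p = 0.0514), while the median was -0.62 (adjusted p = 0.0144) or -0.56 (adjusted p = 0.00987) with arrays centred on ribosomal protein genes or chemoreceptor genes. The synaptotagmin gene snt-4 stood at -1.68 ± 0.61 (SD, n = 4), and the acetylcholinesterase gene ace-2 at 1.71 ± 0.63 (SD, n = 3). The dopamine synthesis gene cat-2 stood at 1.60 ± 1.10 (SD, n = 4). Its call was lost with arrays centred on ribosomal protein genes (1.20, adjusted p = 0.0739) or chemoreceptor genes (1.25, adjusted p = 0.0624). The other higher members, named after their values were seen, were cat-1 (2.83-fold), unc-104 (log2 ratio 0.60) and the serotonin synthesis gene tph-1 (log2 ratio 0.51). Of 51 genes of cilia, 10 were lower and 2 higher (8 and 0 adjusted over the list alone), and the list did not pass (median -0.12, adjusted p = 0.158), with medians of -0.21, -0.07 and -0.07 without preparations 2, 3 and 4. It passed with arrays centred on ribosomal protein genes (-0.51, adjusted p = 0.0443) or chemoreceptor genes (-0.47, adjusted p = 0.0195). For the values as deposited, camera with an estimated correlation gave the cilia list an adjusted p = 0.609. In it nud-2 stood at -1.21 ± 0.74, klp-11 at -1.11 ± 0.29 and the transcription factor gene che-1, a member through its name only, at 1.21 ± 1.09 (SD, n = 4). The call of che-1 was lost without preparation 3 (1.11, adjusted p = 0.0925) or preparation 4 (0.74, adjusted p = 0.076) and with arrays centred on ribosomal protein genes (0.81, adjusted p = 0.218) or chemoreceptor genes (0.86, adjusted p = 0.168).

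Of 41 muscle genes, 16 were higher and 5 lower (16 and 6 adjusted over the list alone), with a median of 0.43 and a camera adjusted p = 0.0248, or adjusted p = 0.672 with an estimated correlation. Without preparation 4 that call was lost (median 0.11, adjusted p = 0.218), and the median was 0.03 with arrays centred on ribosomal protein genes and 0.08 with arrays centred on chemoreceptor genes. Camera, which compares a list with the other genes, still called the muscle list higher with either centring. The troponin T genes tnt-2 and mup-2 stood at 2.25 ± 0.68 and 2.01 ± 0.73, and dim-1 at 1.76 ± 0.59 (SD, n = 4). The myosin heavy chain gene unc-54 was not called at 1.34 (adjusted p = 0.0632), with arrays from 0.20 to 3.54, and stood at 0.605 without preparation 3. It was called without preparation 1 (1.72, adjusted p = 0.0402) and with array weights (2.63, adjusted p = 0.00239). It was also called with the period as a covariate (adjusted p = 0.0209) or as a random block (adjusted p = 0.0419). The array weights were 1.081, 0.308, 4.734 and 0.634 for preparations 1 to 4. The weighted value therefore rests mainly on preparation 3, where unc-54 was 3.54. Of 64 intestinal genes, 17 were higher and 17 lower (18 and 18 adjusted over the list alone), with a median of 0.08 (-0.32 to 0.15 over the settings tried for lists), a mean of -0.08 and an adjusted p = 0.965. The metallothionein gene mtl-1 stood at -3.41 ± 0.87, the ferritin gene ftn-1 at -2.84 ± 0.12 and the fatty acid desaturase gene fat-3 at -2.67 ± 1.12 (SD, n = 4). Of 85 heat shock and stress genes, 24 were higher and 23 lower (24 and 24 adjusted over the list alone), with a median of -0.03 (-0.43 to 0.03 over the settings tried for lists) and an adjusted p = 0.785. Beside hsp-12.6, the glutathione transferase genes gst-9 and gst-41 stood at 3.61 ± 0.56 and -2.77 ± 0.56 (SD, n = 4).

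Lists of the basic cell machinery had medians between -0.02 and 0.43. Of 63 cytosolic ribosomal protein genes, 7 were higher and none lower, and 0 were called when adjusted over the list alone. The list median was 0.38 (camera adjusted p = 0.00137, or adjusted p = 0.672 with an estimated correlation), with 1.10 on preparation 2 against 0.13, 0.04 and 0.34 on preparations 1, 3 and 4. Without preparation 2 the median was 0.15 and the call was lost (adjusted p = 0.0883), and with array weights it was 0.11 (adjusted p = 0.208). The median was 0.04 with arrays centred on chemoreceptor genes, and close to 0 by construction (-0.02) with arrays centred on ribosomal protein genes. Camera, which compares a list with the other genes, still called it higher with ribosomal centring (adjusted p = 0.0333). The largest members were rpl-42 at 1.08 ± 0.38, rps-7 at 0.86 ± 0.68 and rpl-32 at 0.78 ± 0.34 (SD, n = 4). All 3 lost their call with either centring, of which the ribosomal one subtracts the median of their own list. The call of rps-7 was also lost without preparation 1 (0.965) or 3 (0.983), where its value was not lower. That of rpl-32 was lost without preparation 3 (0.606). On preparation 2, rps-7 lay apart at 1.89, and without it the value was 0.52. Of 36 genes of the respiratory chain and ATP synthase, 10 were higher and 1, cox-11 at -0.64, was lower (8 and 1 adjusted over the list alone), with a median of 0.43 and a camera adjusted p = 0.00394, or adjusted p = 0.342 with an estimated correlation. That median was 0.002 or 0.09 with arrays centred on ribosomal protein genes or chemoreceptor genes, and camera still called the list higher with either. The cytochrome c gene cyc-2.2 was the highest member at 3.10 ± 0.57, followed by asg-1 at 1.06 ± 0.26 and atp-1 at 1.04 ± 0.28 (SD, n = 4). Centred on ribosomal protein genes, asg-1 (0.66, adjusted p = 0.125) and atp-1 (0.64, adjusted p = 0.127) lost their calls. Of 30 proteasome genes, 4 were higher and 1 was lower (2 and 0 adjusted over the list alone), with a median of -0.02, a mean of 0.09 and an adjusted p = 0.997, and the median lay between -0.42 and 0.08 over the settings tried for lists. In it rpn-6.2 stood at 1.92 ± 0.82 (SD, n = 4), rpn-13 at 1.09 ± 0.38 (SD, n = 3) and pbs-2 at 0.63 ± 0.31 (SD, n = 4). Both rpn-13 and pbs-2 lost their calls with either centring, and pbs-2 also without preparation 2, 3 or 4 and with every probe kept (adjusted p = 0.0552).

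Of 978 genes in chemoreceptor families, 225 were higher and 12 lower (49 and 6 adjusted over the list alone), with a median of 0.39 and a camera adjusted p = 5.21e-07, or adjusted p = 0.609 with an estimated correlation. The list median was 0.77 on preparation 2 and 0.14, 0.20 and 0.27 on the other 3. Without preparation 2 it was 0.21, with array weights 0.23, and it was -0.02 with arrays centred on ribosomal protein genes. In that last setting camera still called the list higher than the other genes (adjusted p = 0.000497). The list leaves out some families, such as srbc, srab and srxa. With arrays centred on this list, 28 members were called higher and 33 lower. In the values as deposited, members that were at least 2-fold different numbered 60 higher and 5 lower. The gene srb-13 stood at 5.18 ± 0.54 and srz-20 at 2.96 ± 0.44 (SD, n = 4), while srx-95 stood at -2.66 ± 0.16 (SD, n = 3).

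**Figure D3:**
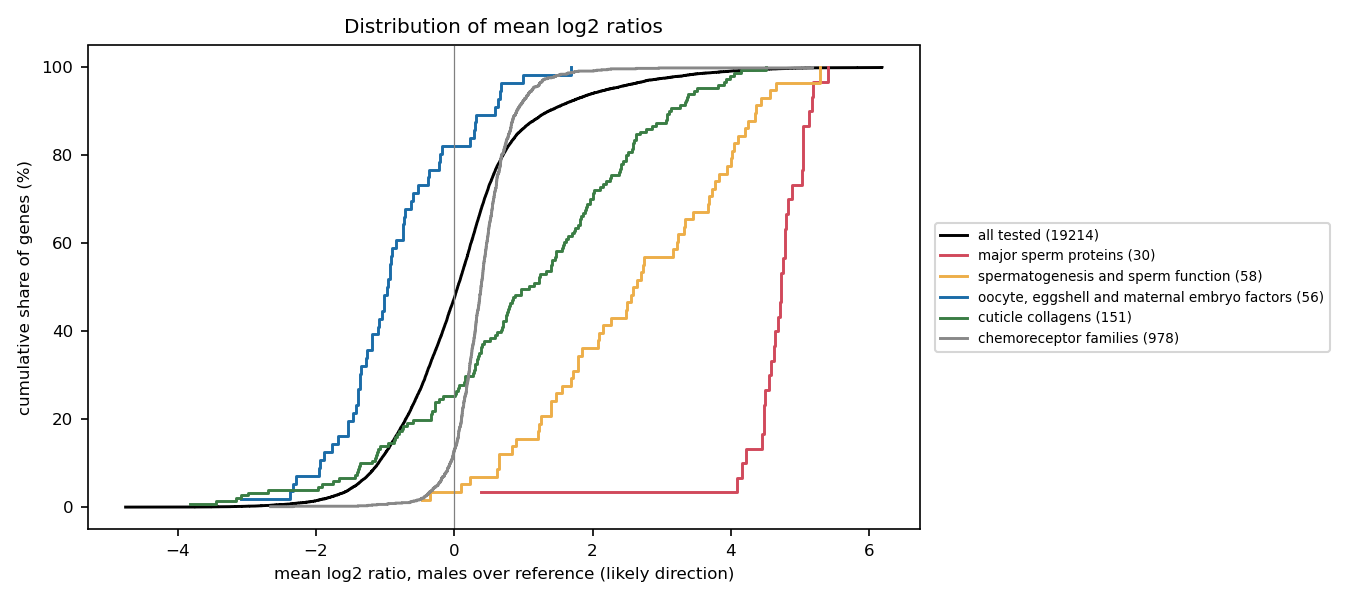
Cumulative share of genes (y axis, percent) by mean log2 ratio (males over reference, likely direction; x axis) for all 19214 tested features and 5 gene lists, with their sizes in brackets. The major sperm protein curve (median 4.72) lies far to the right of all features, the oocyte curve (median -0.97) to the left, and the chemoreceptor curve is steep around its median of 0.39, which becomes -0.02 with arrays centred on ribosomal protein genes.

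The 4 preparations were compared with one another across genes, which are not independent replicates. Pearson's r between arrays was highest for preparations 1 and 3 at 0.898 and lowest for preparations 2 and 4 at 0.707. Of all tested features, 12179 (63.4%) had the same sign on every array. The median SD of a feature over the arrays was 0.40 on the log2 scale, beside a median absolute mean of 0.55. The root mean square deviation from the feature mean was 0.40, 0.56, 0.32 and 0.52 for preparations 1 to 4.

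Gene classes that share the letters of their names were tested beside the fixed lists. Of 148 classes with at least 10 genes, 28 were higher and 22 lower by camera. The 28 included many chemoreceptor families, such as srh (median 0.35) and str (median 0.32), and the ribosomal protein classes rpl and rps. The chemoreceptor and ribosomal protein lists both stood highest on preparation 2, and without that preparation 11 classes were higher. With an estimated correlation camera called 0, with 5 classes at an unadjusted p under 0.05 and adjusted p between 0.47 and 0.999, while fry called 14 higher and 32 lower. For the 22 fixed lists that were tested, camera called 7 higher and 8 lower, 0 with an estimated correlation (0 at an unadjusted p under 0.05), and fry 5 higher and 10 lower. Fry called the zygotic embryo, male tail, cilia and histone lists, which camera did not, and did not call the moulting, muscle, ribosomal protein and chemoreceptor lists. Among the classes, C-type lectins (clec) had 97 of 207 genes higher and 22 lower with a median of 0.55 (adjusted p = 1.48e-05, or adjusted p = 0.47 with an estimated correlation). UDP-glucuronosyltransferases (ugt) had 31 of 61 higher and 5 lower with a median of 0.55 (adjusted p = 0.00256, or adjusted p = 0.9 with an estimated correlation). Centred on ribosomal protein genes or chemoreceptor genes, the clec median was 0.14 or 0.20 and the ugt median 0.15 or 0.20, and both classes were still called higher.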

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

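The 3 tests of why ribosomal protein genes stood higher on preparation 2 were chosen after that result was seen.

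Among 118 groups of 4 values (named genes and list medians), 6 had a value that lay far from the other 3, and chance alone gives about 1 in 20 such groups. On preparation 4, irg-5 stood at 5.30 against 6.10 to 6.18 on the others, and msp-59 at 4.33 against 5.41 to 5.61. On preparation 2, grl-9 stood at -2.52 against -2.09 to -2.03, cwp-2 at 2.05 against 3.95 to 4.30, and rps-7 at 1.89 against 0.50 to 0.55. The median of the sex determination and dosage compensation genes stood at -1.07 on preparation 2 against -0.73 to -0.69.

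The ribosomal protein gene rps-7 went with its list, which was not flagged itself and whose median was 1.10 on preparation 2 and between 0.04 and 0.34 on the other 3. A wider scale of that array was argued against, since after scale normalization its list median still exceeded the next array by 0.525, with an SD of 0.135 among the other 3 medians. A shift of every gene on that array was argued against too, which the close array medians already implied, so that this test adds little to them. Such a shift, or a centring of the array, leaves the distance between the list median and the median of the other features unchanged, and that distance was 1.06 on preparation 2, larger by 0.791 than on the next array, with an SD of 0.114 among the other 3. An offset that depends on the brightness of spots may remain: the chemoreceptor median was also higher on preparation 2, by 0.501, but without spot intensities this cannot be told apart from a difference of the preparation itself. No biological explanation was tested, because the labels name no biological difference between the preparations.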

How the results depend on the processing

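No feature called in the reported setting was called in the opposite direction under any setting that centres, scales, weights, blocks or leaves out arrays. No paired analysis was possible because the series has a single group. The counts that moved by over 1.5 times, and the list medians and genes that changed sign, are given here by setting; the cause was not tested unless named. With arrays centred on ribosomal protein genes, 1624 features were higher, 1558 were at least 2-fold higher, 4119 were at least 2-fold lower and 12 classes were higher. List medians then became -0.191 for male tail genes, -0.32 for intestine, -0.018 for ribosomal proteins (by construction) and -0.015 for chemoreceptors, since every value moved down by 0.40 on average. Centred on chemoreceptor genes, a setting added after the data were seen, the counts were 1993, 1671 and 3979, and the male tail and intestine medians -0.135 and -0.264. The vitellogenin median of the direction check, centred in these 2 ways after the data were seen, was -0.012 and 0.044. Camera, which compares a list with the other genes, called 7 lists higher and 10 lower with either centring, against 7 and 8 in the reported setting. With array weights, 15 classes were higher, the proteasome and heat shock medians were 0.007 and 0.004, and pgl-1 was 0.027. Quantile normalization gave heat shock 0.002. At an adjusted p under 0.01, 2393 features were higher and 2683 lower and 15 classes were higher, fewer because the threshold is stricter. With an estimated correlation 0 lists and 0 classes were called either way, and fry called 14 classes higher. Leaving out 1 preparation gave 2782 (without 3) to 3755 features higher and 3010 (without 3) to 4280 lower, where with 3 arrays fewer calls are made. It gave 11 classes higher without preparation 2, against 27, 26 and 25 without preparations 1, 3 and 4. The number of arrays thus does not account for the 11. The proteasome median was then -0.12 to 0.082, the heat shock median -0.035 to 0.034, and pgl-1 stood at -0.294 to 0.06. A gene with 3 values was not tested without the arrays that held them.

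Of the 101 named genes, 12 lost their call with ribosomal centring, 10 with chemoreceptor centring and 13 at the stricter p; pgl-1 and unc-54 changed with array weights, and unc-54 with the period as a covariate or a random block. The period as a random block gave a correlation of -0.224 between arrays of a pair and called 5044 higher and 5182 lower. Camera results under the limits on missing values are those reported, because camera used only genes with 4 values, and camera was not run with the random block. Signal over background is unknown here, which limits what can be said of faint genes.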

Other observations

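Of the tests reported here, those on neighbouring genes and on the signs of the arrays were set before their results were seen, and those on chemoreceptor and vitellogenin genes after.

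Several classes of gene names outside the fixed lists were called by camera at a preset correlation, and none with an estimated correlation. Genes in them are named after their values were seen. Of 30 vps genes, which act in sorting proteins to lysosomes, 18 were lower and 0 higher (median -0.82, adjusted p = 2.28e-05, or adjusted p = 0.9 with an estimated correlation), among them vps-39 at -1.56 ± 0.18 and vps-22 at -1.41 ± 0.47 (SD, n = 4). Of 16 skr genes, which encode Skp1-related parts of ubiquitin ligases, 11 were lower and 1 higher (median -1.06, adjusted p = 0.00548, or adjusted p = 0.9 with an estimated correlation), led by skr-9 at -2.58 ± 0.76 and skr-8 at -2.46 ± 0.76 (SD, n = 4). Of 10 rgs genes, regulators of G protein signalling, 8 were lower (adjusted p = 0.00556, or adjusted p = 0.9 with an estimated correlation), with rgs-5 at -1.21 ± 0.21 (SD, n = 4). Nuclear hormone receptor genes (nhr) had 76 lower and 22 higher of 234 (median -0.14, adjusted p = 0.0342, or adjusted p = 0.909 with an estimated correlation), with nhr-21 at -2.39 ± 0.17 and nhr-18 at -2.35 ± 0.32 (SD, n = 4); that call was lost without preparation 4 (median -0.13, adjusted p = 0.0882), and the median was -0.54 or -0.49 with arrays centred on ribosomal protein genes or chemoreceptor genes.

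Higher classes included clec, where clec-137 at 5.07 ± 0.86 and clec-138 at 4.77 ± 0.66 (SD, n = 4) followed the lectin genes named before. Among ugt genes, ugt-22 stood at 3.88 ± 0.65 and ugt-63 at 3.81 ± 0.51 (SD, n = 4). Of 56 oac genes, which encode O-acyltransferase homologs, 25 were higher and 6 lower (median 0.60, adjusted p = 0.0223, or adjusted p = 0.9 with an estimated correlation). With arrays centred on ribosomal protein genes the oac call was lost (median 0.20, adjusted p = 0.0621). Of 13 abu genes, 8 were higher and 0 lower (median 1.48, adjusted p = 0.0478, or adjusted p = 0.911 with an estimated correlation), with wide spreads such as abu-2 at 1.90 ± 1.38 (SD, n = 4). The abu call was lost without preparation 2 (1.73, adjusted p = 0.0582) or preparation 4 (0.76, adjusted p = 0.0566) and with array weights (1.29, adjusted p = 0.0548).

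The hypothesis that genes much higher in these males than in the reference lie next to one another was tested on the gene order of assembly WBcel235. Of 406 genes at least 8-fold higher that had a place in it, 77 adjacent pairs were both in the set, against a mean of 9.26 and a highest of 23 over 10000 shuffles (permutation p = 1e-04, the smallest they can give). Pairs of the same gene class did not make up the excess, since 61 pairs of different classes or without a class name remained, against a mean of 8.51 (permutation p = 1e-04). Genes at least 2-fold lower were also adjacent more often, with 377 pairs against a mean of 237.55 (permutation p = 1e-04). Related neighbours without a class name, shared hybridization between similar sequences, probes that span neighbouring genes, and transcription of neighbours as a unit may each contribute to the 77 pairs and were not separated.

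The chemoreceptor families of the fixed list lay above 0 together, with 852 of 978 genes (87.1%) above 0. Of the 16 families in that list with at least 10 members, 14 had their highest median on preparation 2, as the list as a whole did. A zero point that does not hold for faint spots cannot be told apart from a difference of the preparations, since spot intensities were not used here. A rise of some receptor genes with the others unshifted stays open, since members that were not called had a median of 0.296 over the means, but 0.08, 0.68, 0.11 and 0.17 on preparations 1 to 4. Of the 60 members called at least 2-fold higher, 23 were still called with arrays centred on the list; the other 37 fell from a median of 1.23 (median SD 0.88) to 0.86 (median SD 0.94), and their calls ended through the lower value and the wider spread, which the subtraction alone also brings. For srb-13 an offset of the size of the list medians (0.14 to 0.77) is too small to account for its value. It stayed at 4.839 ± 0.795 (SD, n = 4) after centring. As the highest member of the list, it could not have come near 0 through that subtraction. The test thus cannot decide on a larger offset of that spot alone, and expression in males remains a hypothesis for srb-13.

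The vitellogenin genes split, with vit-6 above 0 and vit-2 below 0 on every array. Hermaphrodites carried over into the male preparations, in a share above that of the reference, would bring oocyte transcripts too. They are argued against as the whole cause of the vit-6 value, since the oocyte list median averaged -0.922 ± 0.143 (SD, n = 4) over the arrays. An offset shared with other abundant transcripts stays open for vit-6. With arrays centred on ribosomal protein genes it fell from 0.91 ± 0.44 to 0.505 ± 0.572 (SD, n = 4), and its call ended (adjusted p = 0.24) through the lower value and the wider spread. That setting assumes that ribosomal protein genes did not change, and it lowers every gene. A difference of males, of the him-5 mutation or of stage remains open for both genes and was not tested.

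With the signs of the 4 arrays assigned in each of 8 distinct ways, only 1, the real one, called as many as 8777 features with limma. The highest of the others called 0, with 428 at an unadjusted p under 0.05. A number of 8 assignments is too few for a share under 0.05.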
